A study of Homo sapiens with 6 samples.

How the data were processed

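RNA sequencing libraries were made from SiHa cells, an established human cervical cancer cell line that carries human papillomavirus. Per the labels' protocols, the cells were transfected with a control siRNA or with an siRNA against PTBP1 and collected 72 h later, total RNA was extracted with TRIzol, and Illumina libraries were prepared. There were 3 control and 3 PTBP1 siRNA libraries. The labels number the libraries of each group 1 to 3 and do not say whether the numbers stand for separate cultures, for replicates of one siRNA or for siRNAs of different sequence, so the p-values measure only the spread between these libraries, which may be technical.

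Reads were processed with Trimmomatic and HISAT2 on the hg19 build, per the submitters' processing notes. The counter, the expression estimator, the annotation and the test behind the deposited table are not given in the sources used here. One table was analysed. It lists 6027 genes with their symbols and NCBI Gene IDs. Per the file headers it holds an expression signal for each library, and the header gives no unit for it. The deposited signal is scaled to library size and to gene length, and FPKM and TPM could not be told apart because only part of the genes are listed. The deposited group means are a second signal, which the values show to be read counts divided by a size factor per library. The authors also deposited a fold change (a ratio of these group means), its log2 value, and for each gene a p-value and an adjusted p-value.

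The deposited table is a selection. All of its genes have a deposited p-value under 0.05, the largest being 0.0499, and a deposited fold of at least 1.2 in either direction, with a smallest fold of 1.20. The ratios of adjusted to unadjusted p-values in the authors' deposited table gave whole ranks, within 0.02, for 93.9% of genes if the authors adjusted over 15855 genes, against 31.4% for the next best number that is no multiple of it. The listed genes are thus 38.0% of those the authors tested. A gene that is not listed was not analysed here and is not known to be unchanged. Because every listed gene had already been selected for a difference between the groups, the number of changed genes below describes how the selected genes behave in a second test and is no estimate for the transcriptome, and list tests compare a list's listed members with the other listed genes.

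The depth of the libraries is not given. The deposited group means were searched for whole reads: each is the sum of 3 whole numbers, 1 per library, each divided by that library's size factor and by 3. Of 12040 group means, 11985 (99.5%) had exactly 1 solution within a relative tolerance of 8e-14, 1 had none, 54 were above the search limit and 0 had 2 or more. Of 595 decoy values, 1 had a solution. Whole reads in all 6 libraries came out for 5989 genes. Those 5989 genes held between 7723094 and 8973466 reads per library. These sums leave out listed genes without recovered reads, FTH1 among them, and are not the depth of the whole library. The size factors ranged from 0.951 to 1.10.

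The main test was limma 3.58.1 (R 4.3.3) with an intensity trend on log2(signal + 1), over genes with a mean signal of at least 1 across the 6 libraries, with no covariates. Adjusted p-values are Benjamini-Hochberg values and the threshold was 0.05. Log2 fold changes with their standard errors (SE) are on the log2(signal + 1) scale, which understates the change of low genes. Folds are ratios of mean signals. A count-based test had been planned for a table of counts, and the test planned for normalized values was used because the table holds no counts per library. The main test, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. For PTBP1, its paralogs and CDCP1 an exact two-sided permutation test of the 6 signals was run as well. Its smallest possible p with 3 against 3 libraries is 0.1.

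Genes were named by this rule: PTBP1, PTBP2, PTBP3 and CDCP1 always; the 10 risen and the 10 fallen genes with the largest change among those past the threshold with a mean signal of at least 5 and no overlap between the groups; the 3 members of each discussed list with the smallest p; and the 5 genes with the smallest p of all. Other list members are named where they are the exceptions to a list's direction, and these were chosen after their values were seen. Some genes that the rule names are not reported here. The 30 lists cover PTB proteins, reported PTBP1 targets, CDCP1 partners, neuronal, REST, epithelial, mesenchymal, keratinocyte, matrix protease, integrin and actin genes, cell cycle, p53 and apoptosis genes, interferon, NF-kB, immediate early, ATF4, glycolysis, cholesterol, splicing factor, decay, Hippo, histone, ribosomal and mitochondrial genes, and markers of fibroblasts, blood cells and endothelium. The 25 lists with at least 5 tested members were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry.

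The steps were tested on simulated data with 4976 genes, of which 200 were changed. The test recovered 84.8% of the changes of 0.5 on the log2 scale, 98.5% of those of 1 and 100% of those of 2, and 7 of its 196 calls (3.57%) were false. It made 0 calls in data with no change. Of 25 simulated lists 1 was given a change, and 0 of the unchanged lists were called. The genes were simulated as independent and few of them were changed, unlike those of the table. The simulation therefore does not test how often camera makes false calls among correlated genes.

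Alternatives were quantile normalization, centring on the median, limma without the trend, other minimum signals, pseudocounts of 0.1 and 0.01, the replicate number as a block, leaving out each library, library weights, and a fold of at least 2. Added after the data were seen were limma's voom on the recovered reads, adjustment over 15855 genes, and a correction of each library for a loess trend on GC content. GC content was that of the longest protein-coding transcript in GENCODE release 29. The build of that reference differs from hg19, so no coordinates are given. The alternatives planned for counts per library were not run. The circular RNA named in the series title was not analysed here.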

Results

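The data were expression signals of 6027 genes in 6 RNA sequencing libraries of SiHa cells, 3 from cells given a control siRNA and 3 from cells given an siRNA against PTBP1, collected 72 h after transfection. PTBP1 is an RNA-binding protein that represses many exons during splicing. The series set out to find messenger RNAs downstream of PTBP1, and its title names CDCP1, a transmembrane protein that is phosphorylated by SRC family kinases. The 5989 listed genes with reads recovered in all 6 libraries held 8252405, 8973466 and 7723094 reads in control libraries 1 to 3. In PTBP1 siRNA libraries 1 to 3 the same genes held 8339858, 8158582 and 7864296. The highly expressed FTH1 is not among them. Across the tested genes the correlation of log2 signals was 0.993 to 0.998 within groups and 0.929 to 0.950 between them. The control libraries varied more, with correlations of 0.9931 to 0.9963, against 0.9971 to 0.9978 for the PTBP1 siRNA libraries.

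The target of the siRNA was lower in every PTBP1 siRNA library. The PTBP1 signal (NCBI Gene 5725) was 124.6, 122.3 and 123.0 in the control libraries and 39.1, 31.8 and 32.0 in the PTBP1 siRNA libraries, or 123.3 ± 1.22 against 34.3 ± 4.17 (SD, n = 3 each), and the signal left was 0.278 of the control. Its log2 fold change was -1.82 (SE 0.074; limma, Benjamini-Hochberg adjusted p = 2.77e-07). Both listed paralogs rose. PTBP2 (NCBI Gene 58155), the paralog most active in neurons, rose 15-fold from 3.28 ± 0.889 to 49.3 ± 2.41 (SD, n = 3 each), a log2 fold change of 3.58 (SE 0.136; limma, Benjamini-Hochberg adjusted p = 2.39e-07). PTBP3 (NCBI Gene 9991) rose 1.54-fold from 27.4 ± 1.57 to 42.3 ± 1.68 (SD, n = 3 each; log2 fold change 0.61, SE 0.053; limma, Benjamini-Hochberg adjusted p = 1.39e-05), and its log2 fold change was 0.19 after a correction for GC content, with the call kept.

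CDCP1 (NCBI Gene 64866) fell. Its signal was 31.0, 29.7 and 28.95 in the control libraries and 9.77, 9.39 and 9.52 in the PTBP1 siRNA libraries, so that 29.9 ± 1.03 dropped to 9.56 ± 0.195 (SD, n = 3 each), 0.32 of the control. The log2 fold change was -1.55 (SE 0.047; limma, Benjamini-Hochberg adjusted p = 9.24e-08). For PTBP1, PTBP2, PTBP3 and CDCP1 the groups did not overlap and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. In the authors' deposited table the log2 fold changes of these genes were -1.97, 3.83, 0.71 and -1.69 in that order.

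**Figure D1:**
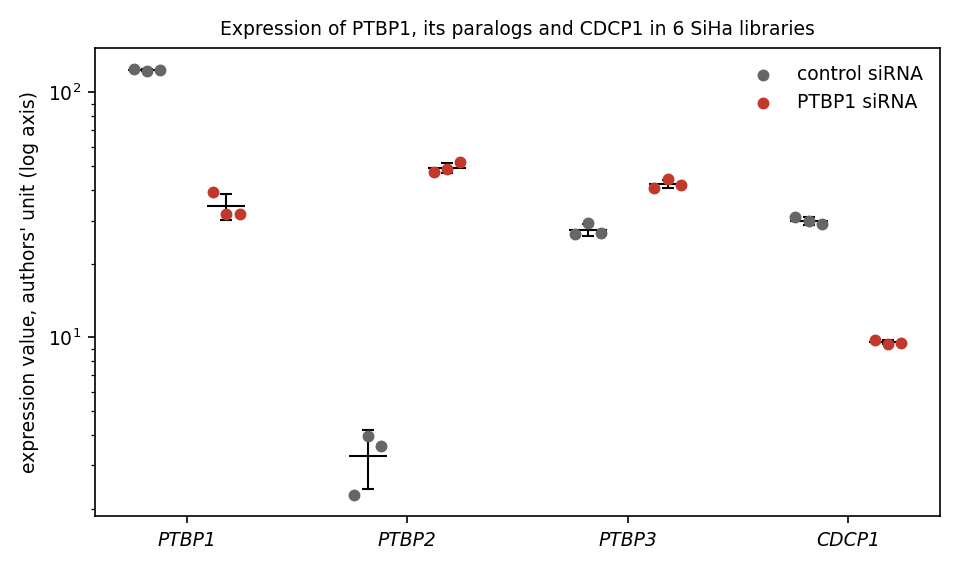
Expression signal of PTBP1, PTBP2, PTBP3 and CDCP1 on a log axis, in the authors' unit, with 1 point per library, a black bar for the mean of 3 libraries and error bars of 1 SD. PTBP1 and CDCP1 are lower in all 3 PTBP1 siRNA libraries than in the controls, and PTBP2 and PTBP3 are higher.

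Of the 4976 genes tested, 2648 rose and 2213 fell (limma, Benjamini-Hochberg adjusted p under 0.05), and 90 of these rose and 147 fell at least 2-fold on the log2(signal + 1) scale. The 3 libraries of a group did not overlap with the other group for 97.0% of the genes, against 10% by chance. These shares follow from the table, which lists genes that the authors had already selected for a difference. The authors' deposited table lists 3003 genes as up and 3024 as down, 248 and 645 of them with an adjusted p under 0.05 and a fold of at least 2. The direction differed between this test and the authors' deposited table for 3 genes, 1 of them past the threshold. Fold changes followed GC content: 95.2% of the 495 genes of lowest GC content had a positive fold change, with a median log2 fold change of 0.43, against 38.6% of the 495 genes of highest GC content, with a median of -0.19. After a correction for GC content 1834 genes rose and 1941 fell.

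Beside PTBP2, 7 of the 10 largest rises were histone genes: HIST1H4H (6.79-fold), HIST2H2BE (4.59-fold), HIST1H2AC (4.14-fold), HIST1H2BJ (3.94-fold), HIST1H2BD (4.16-fold), HIST1H2BK (3.43-fold) and HIST1H1C (3.42-fold). The other two were PTGS2, which encodes the inducible cyclooxygenase and rose 5.43-fold from 12.8 ± 0.837 to 69.7 ± 7.47 (SD, n = 3 each), and IFRD1, a transcriptional regulator, which rose 3.92-fold from 16.9 ± 0.384 to 66.4 ± 2.79. The largest fall was that of RPS20, a protein of the small ribosomal subunit, from 196 ± 10.1 to 22.6 ± 3.81, or 8.65-fold. FTH1, the heavy chain of the iron store ferritin, fell 4.49-fold from 9080 to 2021, and its share of the listed signal was 6.75% to 7.52% in the control libraries and 1.58% to 1.82% in the PTBP1 siRNA libraries. STC2, a secreted glycoprotein, fell 5.52-fold, ASNS, asparagine synthetase, 5.30-fold, and PSCA, a membrane-anchored antigen, 5.91-fold. SPINK6, a protease inhibitor, fell 4.14-fold, the water and glycerol channel AQP3 4.53-fold, NDRG1 4.27-fold and the protease inhibitor CSTA 3.99-fold. PTBP1 itself completed the 10. The 5 smallest p-values belonged to HIST1H2AC, HIST1H1C, IFRD1, ASNS and FTH1, each with a limma, Benjamini-Hochberg adjusted p of 4.84e-08.

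Among the gene lists, 11 of 25 passed camera's test at its preset correlation, 1 up and 10 down, and 0 did with an estimated correlation, where 6 had an unadjusted p under 0.05. The estimate was -0.002 for the histone list, -0.052 for ribosomal proteins, -0.064 for integrins and laminins and -0.085 for epithelial genes. These lie below the preset 0.01, so correlation among genes does not account for the calls these lists lost. For the rest of the 11 it was 0.029 to 0.263. The counts adjusted over the list alone were the same as those over all genes for the 25 lists. All list counts cover only listed members. Not listed were 18 of 28 ribosomal protein symbols, 17 of 30 for S phase, 16 of 30 for mitosis and 11 of 28 for the ATF4 list. Tested genes on the list of the integrated stress response driven by ATF4 and of the unfolded protein response fell together. HSPA5, HSP90B1, DNAJB9, SDF2L1, CALR, CRELD2, MANF and SEL1L on that list were not tested. The fall thus does not cover the unfolded protein response as a whole, for which XBP1, HERPUD1, EDEM1 and PDIA4 had log2 fold changes of -0.84, -0.89, -0.30 and -0.24. All 16 tested members fell, with a median log2 fold change of -0.87 (limma camera, Benjamini-Hochberg adjusted p = 5.3e-06; adjusted p = 0.18 with an estimated correlation). ASNS fell from 117 ± 8.16 to 22.04 ± 0.937 (SD, n = 3 each), and the serine synthesis enzymes PHGDH and PSAT1 fell 3.63-fold and 2.71-fold. Genes of glycolysis and the hypoxia response fell in 14 of 15 cases, with a median of -0.64 (camera adjusted p = 0.000239; adjusted p = 0.18 with an estimated correlation). Examples were the glycolytic enzyme PGAM1 (3.07-fold lower), the hypoxia-inducible factor subunit HIF1A (1.98-fold lower) and the hypoxia-responsive NDRG1. The other glycolytic enzymes that fell did so by less than PGAM1, from PGK1 (1.56-fold) to PFKL (1.12-fold). Hexokinase HK1 was the member that rose. After the GC correction the medians of these lists were -0.77 and -0.50. The median of the glycolysis and hypoxia list was -0.36 at a mean signal of at least 5 and -1.21 with voom on the recovered reads, with the call kept. Both settings change which members are tested. Voom leaves out genes without recovered reads in all 6 libraries, HIF1A among them, and its values are not on the log2(signal + 1) scale.

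All 16 tested members of the histone list rose, with a median log2 fold change of 1.73 (limma camera, Benjamini-Hochberg adjusted p = 7.6e-05; adjusted p = 0.17 with an estimated correlation). HIST1H1C, a linker histone, rose from 85.2 ± 3.38 to 292 ± 7.63 (SD, n = 3 each) and HIST1H2AC from 35.3 ± 1.26 to 146 ± 5.50. These genes have near-identical copies between which reads can be split, so the level of a single copy is uncertain. HIST1H2BJ is not on that list. Of the other histone genes, chosen after their values were seen, H2AFZ, H2AFV, H1FX and H2AFX, which encode replacement variants, fell, with log2 fold changes of -0.58, -0.55, -0.36 and -0.33, and H2AFJ rose (log2 fold change 0.39). Cell cycle genes moved the other way. Of 13 tested S phase genes 12 fell, with a median of -0.43 (camera adjusted p = 0.00204; adjusted p = 0.31 with an estimated correlation), among them the ribonucleotide reductase subunit RRM2 (1.60-fold lower), the flap endonuclease FEN1 (1.5-fold lower) and the replication clamp PCNA (1.40-fold lower), and RFC3 rose. Of 14 mitosis genes 12 fell, with a median of -0.31 (camera adjusted p = 0.00624; adjusted p = 0.18 with an estimated correlation), among them KIF20A, CCNB1 and MKI67, while CENPE and TTK rose. After the GC correction the medians were 1.82 for histone, -0.41 for S phase and -0.29 for mitosis genes.

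Of 14 integrin and laminin genes 12 fell, with a median log2 fold change of -0.53 (limma camera, Benjamini-Hochberg adjusted p = 0.00204; adjusted p = 0.17 with an estimated correlation). The laminin chain LAMB3 fell 2.99-fold, the fibronectin receptor subunit ITGA5 fell 1.98-fold, and ITGB8 and ITGB1 rose. Of 10 matrix proteases and inhibitors 9 fell, with a median of -0.43 (camera adjusted p = 0.00459; adjusted p = 0.31 with an estimated correlation). The gelatinase MMP2 fell 3.45-fold, and the list's other leading members were inhibitors, TIMP1 (3.21-fold lower) and TIMP2 (1.95-fold lower). The collagenase MMP1 rose. Of 10 epithelial genes 9 fell, with a median of -0.39 (camera adjusted p = 0.0150; adjusted p = 0.18 with an estimated correlation), among them the keratins KRT19 (2.23-fold lower) and KRT8 (1.59-fold lower), while the adhesion molecule EPCAM rose 1.88-fold. The medians after the GC correction were -0.49, -0.32 and -0.37. With voom on the recovered reads the median was -0.90 for the integrin and laminin list and -0.58 for the epithelial list.

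Interferon-stimulated genes fell in 16 of 18 cases, with a median log2 fold change of -0.47 (limma camera, Benjamini-Hochberg adjusted p = 0.00187; adjusted p = 0.31 with an estimated correlation). OASL fell 5.53-fold, MX2 3.37-fold and IFIT2 3.19-fold, all from control means below 10, and USP18 and IFI35 rose. All 10 tested members of the ribosomal protein list fell, with a median of -0.28 (camera adjusted p = 0.00170; adjusted p = 0.17 with an estimated correlation), and the list lost its call under quantile normalization (adjusted p = 0.133). Beside RPS20, RPL3 fell 1.48-fold and RPLP1 1.41-fold, and RPLP1 also lost its call under quantile normalization. Over all 30 ribosomal protein genes tested other than RPS20, on the list or not, 26 fell and 2 rose. Of 15 immediate early genes and their feedback regulators 12 fell, with a median of -0.41 (camera adjusted p = 0.0495; adjusted p = 0.32 with an estimated correlation). PHLDA1 fell 2.21-fold, ETV5 1.71-fold and FOSL2 1.47-fold, and IER2, SPRED1 and JUN rose. This call was lost without control library 2 (adjusted p = 0.0511) or without PTBP1 siRNA library 1 (adjusted p = 0.0725), and in 4 other settings, the GC correction among them (adjusted p = 0.216). The medians after the GC correction were -0.43 for interferon-stimulated and -0.29 for ribosomal protein genes.

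**Figure D2:**
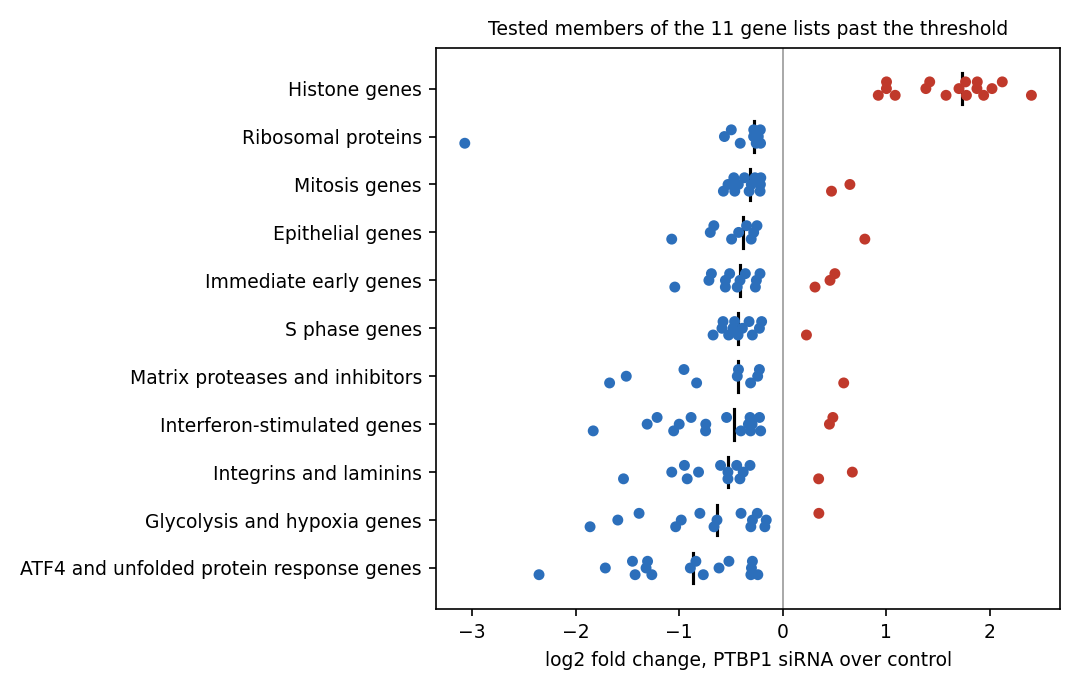
Log2 fold change, on the log2(signal + 1) scale, of each tested member of the 11 lists past the threshold, PTBP1 siRNA over control siRNA. Each point is a gene, red for a rise and blue for a fall at an adjusted p under 0.05, and the black bar is the list's median, from -0.87 for ATF4 and unfolded protein response genes to 1.73 for histone genes.

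The remaining 14 tested lists did not pass. Of 15 genes in the list of CDCP1 and its partners, 4 rose and 10 fell (limma camera, Benjamini-Hochberg adjusted p = 0.181), with the receptor kinase AXL 1.98-fold and the syndecan SDC4 1.41-fold lower, and FASN did not pass (log2 fold change -0.09). Of 15 mesenchymal genes 5 rose and 9 fell, with TGFBI 2.29-fold lower, the matricellular gene CYR61 2.0-fold higher and TGFB1 not past the threshold (log2 fold change -0.08). Among 6 genes of the PTB family and its partners 5 rose and PTBP1 fell. Of 15 reported PTBP1 splicing and decay targets 8 rose and 7 fell, with TPM2, a tropomyosin, 2.15-fold higher. Of 11 actin cytoskeleton genes 3 rose and 8 fell, with TPM4 2.26-fold higher and CALD1 2.97-fold lower. Of 7 neuronal genes 2 rose and 5 fell, with MAP2 2.04-fold higher and TUBB3 and ENO2 1.71-fold and 1.77-fold lower. Of 13 NF-kB and cytokine genes 5 rose and 8 fell, among them PTGS2 and RELB (1.86-fold higher) and IL1B (2.93-fold lower). Of 13 Hippo and TGF-beta targets 5 rose and 8 fell, with ID3 1.56-fold higher. Of 9 cholesterol genes 2 rose and 7 fell, with CYP51A1 1.61-fold higher and INSIG1 1.68-fold lower. Of 9 apoptosis regulators 6 rose and 3 fell, with BIRC2 1.94-fold higher (log2 fold change 0.93, and 0.57 after the GC correction) and BNIP3L 2.11-fold lower. Of 15 p53 targets 6 rose and 9 fell, with SESN2, CDKN1A and DDB2 1.80-fold, 1.53-fold and 1.52-fold lower. Of 11 splicing factors 7 rose and 4 fell, with HNRNPD 1.26-fold higher (log2 fold change 0.33, and 0.16 after the GC correction) and RBFOX2 and HNRNPA1 1.49-fold and 1.25-fold lower, and the median of that list was 0.31 and -0.09 after the GC correction. Of 10 genes of nonsense-mediated decay 5 rose and 5 fell, with CARS, ATF4 and SRSF2 1.66-fold, 1.44-fold and 1.22-fold lower, and their median was 0.01 (-0.05 to 0.05 over the alternatives) and their mean -0.02. Of 9 genes of REST and its corepressors 5 rose and 4 fell, with SMARCE1 1.56-fold and SMARCA4 1.40-fold higher and CTDSP2 1.68-fold lower, and the median was 0.22 where camera's direction was down, and -0.02 after the GC correction. The adjusted p of these lists, from limma's camera with Benjamini-Hochberg adjustment, ranged from 0.181 to 0.919.

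The other 5 lists had too few tested members. Of the keratinocyte differentiation genes 4 were tested and fell (log2 fold changes of -0.78 for SFN, -1.85 for CSTA, -0.99 for S100A9 and -0.64 for KRT16). Of the blood cell markers 2 were tested and fell (log2 fold changes of -0.68 for CD14 and -0.28 for CD68). No mitochondrial genome gene is listed, and 0 fibroblast and 0 endothelial markers reached the minimum signal.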

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

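PTBP1 and CDCP1 kept their direction and their call in all alternatives, with log2 fold changes from -1.98 to -1.70 and from -1.68 to -1.41 and the highest adjusted p at 1.13e-05 for PTBP1. The number of changed genes was 4861. It was 3207 at a mean signal of at least 5 and 237 with a fold of at least 2 (90 rose and 147 fell), both by their construction. It was 4739 under quantile normalization, 4796 after centring, 5749 without a minimum, 4936 with limma's voom on the recovered reads, 4602 when adjusted over 15855 genes and 3775 after the GC correction, the last 3 chosen after seeing the data. After the GC correction 1834 genes rose and 1941 fell, and of the 3754 genes called both ways 95 had the other direction. Leaving out 1 library gave 4644 to 4822 changed genes, log2 fold changes of -1.92 to -1.77 for PTBP1 and -1.57 to -1.52 for CDCP1, and 10 to 11 gene lists. Of 25 lists 11 passed. With an estimated correlation 0 passed, and with fry 23 did. Fry does not compare a list with the other listed genes, and every listed gene had been selected for a difference, so calls by fry carry little weight. The list of nonsense-mediated decay passed with fry (Benjamini-Hochberg adjusted p = 0.00973) although 5 of its genes rose and 5 fell. The CDCP1 list passed with voom (adjusted p = 0.0456, with a range of 0.0456 to 0.538 over its camera settings at the preset correlation) and with fry (adjusted p = 1.41e-05), and had an adjusted p of 0.312 with an estimated correlation. The cause of the call with voom was not tested. For the named genes 1412 comparisons with an alternative kept their call, 1 lost it (RPLP1 under quantile normalization) and none reversed. For the lists 443 comparisons kept their status, called or not, 18 lost a call and 13 gained one. No list with a call in either setting reversed. Turns of direction in lists without a call were not counted as reversals. Medians of such lists could change sign, as that of the p53 targets did (-0.34 to 0.26).

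With the replicate number as a block 4874 genes changed, and no list or named gene changed its call. The labels do not say whether the numbers pair the libraries. The correlations of same-numbered libraries' deviations were 0.165, 0.190 and 0.079. For control libraries 1 to 3 the highest correlations with another number were 0.0041, -0.059 and -0.0185. Each library thus correlated best with the other group's library of its own number, which is a weak hint of pairing from the data and no proof. Deviations from a group's mean cancel out, so high correlations at the same number force low ones at the others. How often such a match arises without pairing was not tested. The alternatives planned for counts per library (other size factors and a count model) were not run. The recovered reads were tested for changed genes with voom in their place. Of the 10 splits of the 6 libraries into groups of 3, only 1, the real one, gave 4861 changed genes, and the highest other split gave 0. The listed genes had been selected for a difference between the real groups, so this outcome was largely fixed in advance and decides nothing. Besides, 10 splits are too few for a share under 0.05. The bound for this test was written down after its result was seen. What depth limits was not tested, as the depth of the whole libraries is not given.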

Other observations

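All tests in this part were chosen after the results were seen. Pathway annotations in the table gave 247 KEGG pathways with at least 10 tested genes. With limma's camera at its preset correlation and Benjamini-Hochberg adjustment 1 pathway was up and 4 were down, and 0 passed with an estimated correlation (lowest adjusted p = 0.558, with 19 at an unadjusted p under 0.05). Genes of ribosome biogenesis rose in 33 of 37 cases (adjusted p = 0.0121), led by UTP4, GTPBP4 and NHP2. In the Ribosome pathway 21 of 52 genes rose and 29 fell, and it did not pass (adjusted p = 0.414). Genes annotated to complement and coagulation fell in 15 of 15 cases (adjusted p = 0.00116), among them complement factor CFB and CD55. Genes of the hematopoietic cell lineage pathway fell in 19 of 21 cases (adjusted p = 0.00116); its leading members, ITGA5, CD55 and IL1B, encode an integrin, a complement regulator and a cytokine that are not restricted to blood cells. ECM-receptor genes fell in 22 of 27 cases (adjusted p = 0.00833). Lysosome genes fell in 39 of 53 cases (adjusted p = 0.0394) and lost the call after the GC correction (adjusted p = 0.118).

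Signal per read, the ratio of the deposited signal to the recovered reads, can move with the estimated transcript length. As the counter and the expression estimator are not given, other differences between signal and reads could move it too. Which of these moved it was not tested. Signal per read differed between the groups for 179 of 4826 genes with at least 50 reads per library (limma, Benjamini-Hochberg adjusted p under 0.05). It was higher in the PTBP1 siRNA libraries for 153 of these genes and lower for 26. The largest log2 changes were 1.23 for TPRKB, 0.50 for FKBP11 and 0.45 for UBE2E1. Of 13 reported PTBP1 targets 1 differed, TPM1, at -0.31 (adjusted p = 0.0211), against 3.71% of all genes (Fisher's exact p = 0.389). That count rests on the threshold. FLNA, TPM2, FGFR1 and SRC had limma, Benjamini-Hochberg adjusted p-values of 0.0512, 0.0554, 0.0581 and 0.0609. Those of the remaining targets ran from 0.104 to 0.384. Over all 4826 genes 1793 had an unadjusted limma p under 0.05. The comparison does not show that the targets were unaffected.

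Fold changes fell with GC content (Spearman correlation -0.30 across 4943 genes, which are not independent replicates), but not evenly, as the share of positive fold changes dropped from 95.2% in the lowest of 10 bins by GC content to 30.4% in bin 7 and was 38.6% in bin 10, where 190 genes rose and 277 fell. The recovered reads show the same trend (-0.435), which argues against the length-scaled estimate as its source. The slopes of log2 signal per 10 points of GC were 0.129, 0.048 and 0.090 in the control libraries and -0.070, -0.114 and -0.084 in the PTBP1 siRNA libraries, a gap of 0.118 against a widest range of 0.081 within a group. That gap would have argued against a bias of single libraries, but this reading was withdrawn after the value was seen, because listed genes were selected for a difference between the groups, which widens such a gap. Single-library bias, a preparation bias shared by one group (exact permutation p = 0.1, the smallest possible) and an effect of the knockdown on AT-rich transcripts cannot be told apart.

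Replication-dependent histone genes rose while 12 of the 13 tested S phase genes fell, with a median of -0.43. For these tested genes, this argues against a larger share of cells in S phase. The table does not list 17 of the 30 S phase symbols, and its selection leaves out genes with small folds, so the list as a whole may have moved less. In the authors' deposited table all 32 listed histone genes of this class have a rise and 0 a fall, which argues against reads merely moving from one listed copy to another. It cannot exclude that reads of some rising copies were split over near-identical ones, which would make all of them rise. Copies without a selected difference are not listed. How many separate copies rose thus stays uncertain. The GC trend is argued against by the median of 1.82 after the correction, against 1.73 before. Capture of more RNA without poly(A) tails, which may raise histone messages, stays open because 0 other RNAs of that kind are listed. More polyadenylated or more stable histone messages after the knockdown also stay open and were not tested.

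RPS20 fell by far more than the other 30 tested ribosomal protein genes, whose log2 fold changes ran from -0.56 to 0.45 (26 fell and 2 rose), and lay -2.51 from the lowest of them, which argues against a fall of the class as the whole cause. The recovered reads fell as much (log2 fold change -3.06), which argues against the length-scaled estimate. Unintended silencing of RPS20 by the siRNA may account for it and stays open, as does an effect of the loss of PTBP1. The highest PTBP1 siRNA library was 1.37 times the lowest for RPS20, and the labels do not say whether the libraries received siRNAs of different sequence.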
